A study of Caenorhabditis elegans with 8 samples.

How the data were processed

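The deposited data hold 8 tables of small RNA reads mapped to reference sequences of Caenorhabditis elegans. They cover miRNAs, mRNAs, noncoding RNAs, piRNAs and transposons, and also the 26G reads on mRNA, the 26G reads on noncoding RNA and the 21U reads on piRNA. Per the file headers, each library has a sense and an antisense column, for which the headers name no unit. These deposited columns hold whole read numbers, labelled expected counts here, and per the file headers come from a read file mapped to a reference file. Rounding changed no value, so they were treated as counts. Each value equalled the sum of the deposited size histogram beside it, which lists read lengths and first bases and is no measurement of its own. The total line of each table was left out of the gene tests, while class shares, their permutation tests and the total mapped reads used it. In the transposon table that line exceeds the sum of the listed entries, so the transposon share was also computed from listed entries, an alternative chosen after seeing the data. The tables of the authors' own comparisons hold, per the file headers, a signal (the mean of counts divided by DESeq size factors), a log2 fold change with its SE in log2, a score (the Wald statistic) and raw and adjusted p-values. These deposited values were copied and not recomputed. The submitters' processing notes name cutadapt, Bowtie and DESeq, with versions not given in the sources used here.

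The reference names in the tables carry WormBase release labels. Coordinates are given for WBcel235 from annotation release 115, matched through the WormBase gene identifier. All 8 libraries carry 1 batch date in the labels, so no batch could be compared. Group and replicate number follow the column labels, which place every per-sample column: 0 were left without a sample. The read files named in the headers of both WT libraries and of G1685D replicates 2 and 3 carry other replicate numbers than those labels. Groups are the same either way, but the replicate block, the pairing check and each named left-out library rest on the column label. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

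Before the data were examined, the test, the scaling, the count filter, the alternatives, the gene lists and the rule for named genes were fixed. The tests were edgeR quasi-likelihood F tests with the 8 libraries in 1 fit of 3 groups (WT 2, R3K 3 and G1685D 3), two-sided, with Benjamini-Hochberg adjustment within each table and contrast and a threshold of 0.05. One set of TMM factors, computed over the combined miRNA, mRNA, noncoding RNA, piRNA and transposon tables, scaled every table, so that a change of a whole class such as 26G reads was not removed. CPM are counts scaled to that effective library size. For genes with several isoforms the isoform with the highest mean was kept. Features entered a test with at least 10 counts in at least 2 libraries. Antisense reads were tested for mRNA, noncoding RNA and transposons, and sense reads for miRNA and 21U reads. That choice of strand was made after the tables were seen, and counts with both strands summed are given among the alternatives.

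The 26 fixed lists were written from general knowledge. The 13 mRNA lists hold ERGO-1 class 26G targets, sperm genes, oocyte genes, meiosis genes, small RNA pathway genes, F-box and MATH family genes, histone genes, collagen genes, vitellogenin and gut genes, body muscle genes, neuron genes, heat shock genes, and cyclin and cell division genes. The 13 miRNA lists hold the let-7, mir-35, lin-4, mir-51, mir-58, mir-64, mir-44, mir-2 and mir-72 families, mirtrons, muscle and neuron miRNAs, and the 5p and the 3p arms. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 on log2 CPM with a prior count of 2, again with an estimated correlation, and with fry, adjusted over the lists of a table and contrast. Smaller lists have values only. Arm use was tested with limma on the log2 ratio of 5p over 3p reads with a pseudocount of 0.5. Class shares were compared with two-sided exact permutation tests, which cannot go below p = 0.1 with these group sizes.

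Named genes followed this rule. For 26G reads on mRNA, all antisense reads on mRNA, and miRNA, and for each mutant against WT, up to 10 features per direction with the lowest p were named among those past an adjusted p of 0.05, with mutant and WT libraries not overlapping and a mean CPM of at least 10 (at least 1 for 26G reads). For each list the 3 tested members with the highest mean CPM were named, plus dcr-1. For 26G reads on noncoding RNA and for transposons, up to 5 per direction were named by the same rule. No piRNA was to be named unless past an adjusted p of 0.05. Counts of 5 or fewer could be named in full. Genes named for R3K against G1685D, for 22G reads, for sense reads and for arm use, and the transposons lower in R3K, were chosen after their values were seen.

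A fold against a group whose libraries are all at 0 was computed against a floor of 3 counts over the group and is written "at least". With 1 to 3 counts over a group, the ratio is given with its 95% counting interval. Medians of lists with such genes are given also with those genes at their bound.

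The alternatives set beforehand were total mapped reads as library size, 21U reads as library size, TMM within the table, DESeq2, no filter on low counts, a replicate block, leaving out each library, arms with a mean of at least 100 reads, and class totals relative to 21U reads. Chosen after seeing the data were isoforms summed, both strands summed, the 21U share of the library as a covariate, the tables of antisense 22G reads (22 nt with a first G) and of sense reads on mRNA, reads of 21 to 23 nt with a first G, the added classes, the sense reads of 18 to 20 nt at 26G targets, and the split of 26G genes by the authors' classes. The covariate was added because libraries within each group differed in their 21U share.

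Some mRNA entries took antisense reads that followed a miRNA entry. Entries were said to track a miRNA when both held at least 500 reads, their reads lay within a share of 0.2 of each other and their correlation over libraries was at least 0.995. The minimum first tried, 0.9, gave 47 entries with 92.9% of antisense mRNA reads, and the minimum used gave 10 entries with 92.7%. That minimum was raised after the entries were seen.

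A self-test with planted changes on simulated counts recovered 37.5% of 4-fold changes and 0% of 2-fold changes in the 26G table in both R3K contrasts. It recovered 76% of 4-fold changes in the mRNA table and 89.7% in the miRNA table for R3K against WT. No pair of libraries was a duplicate: the chi-square per degree of freedom within groups ran from 6.26 upward. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.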

Results

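Small RNA was sequenced from whole hermaphrodites of Caenorhabditis elegans moved at the middle of the last larval stage to 25 °C for 24 hours. The 8 libraries fell into 3 groups: 2 of wild type (WT, the Bristol N2 strain), 3 of R3K, which carries arginine-to-lysine changes in dcr-1, the gene of the small RNA nuclease Dicer, and 3 of G1685D, a dcr-1 change in the RNase III part of the protein. The series title names arginine methylation of the helicase domain of Dicer, the 26G endo-siRNA pathway and oocyte meiosis. The reads summed over all tables were 9292327 and 12982900 in the WT libraries, 5986448, 7656429 and 9224034 in R3K, and 6794796, 6180083 and 5777347 in G1685D. Unless stated otherwise, values are means ± SD over these libraries, log2 fold changes carry their SE, and adjusted p-values come from edgeR.

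To show how reads were divided among small RNA classes, shares of all table reads were compared. Antisense 26G reads on mRNA, siRNAs of 26 nt with a first G, made up 0.109% ± 0.0184 in WT (SD, n = 2), 0.0270% ± 0.00482 in R3K (n = 3) and 0.0336% ± 0.00512 in G1685D (n = 3). The R3K and G1685D means were 0.248 and 0.308 of the WT mean, and every mutant library lay below both WT libraries (two-sided exact permutation p = 0.1 for each, the smallest possible). Antisense 22G reads, the secondary siRNAs of 22 nt, took 0.448% ± 0.0687, 0.421% ± 0.0919 and 0.296% ± 0.0521 in the same order (exact permutation p = 0.8 and 0.1 against WT). miRNA reads took 65.4% ± 1.64 in WT, 68.1% ± 1.27 in R3K and 55.6% ± 1.38 in G1685D (exact permutation p = 0.2 and 0.1). Antisense and sense mRNA reads together took 33.4% ± 2.35, 30.1% ± 1.85 and 42.5% ± 1.96 (exact permutation p = 0.3 and 0.1). Of the antisense mRNA reads 92.7% lay in 10 entries that tracked a miRNA entry, srz-67 with 0.997 of the reads of mir-1-3p among them. The mRNA share is therefore largely not one of siRNAs on mRNA, and the sum over tables used for all shares holds these reads beside those of the miRNAs. Noncoding RNA took 0.219% ± 0.0571, 0.399% ± 0.0898 and 0.786% ± 0.149 (exact permutation p = 0.2 and 0.1), and transposons 0.0411% ± 0.00779, 0.0492% ± 0.0103 and 0.0637% ± 0.00546 (exact permutation p = 0.4 and 0.1). The transposon shares rest on the total line of that table, and with its listed entries summed, an alternative chosen after seeing the data, they were 0.0373% ± 0.00669, 0.0394% ± 0.00858 and 0.0450% ± 0.00494 (exact permutation p = 0.8 and 0.3). The 21U reads of piRNAs took 0.788% ± 0.586, 1.16% ± 0.525 and 0.749% ± 0.505 (exact permutation p = 0.5 and 0.9), a spread within each group larger than the differences between them. Without WT replicate 1 the log2 ratio of the 21U share in R3K over WT was 1.64, and without WT replicate 2 it was -0.0475 (class totals per library, 21U, R3K vs WT).

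**Figure D1:**
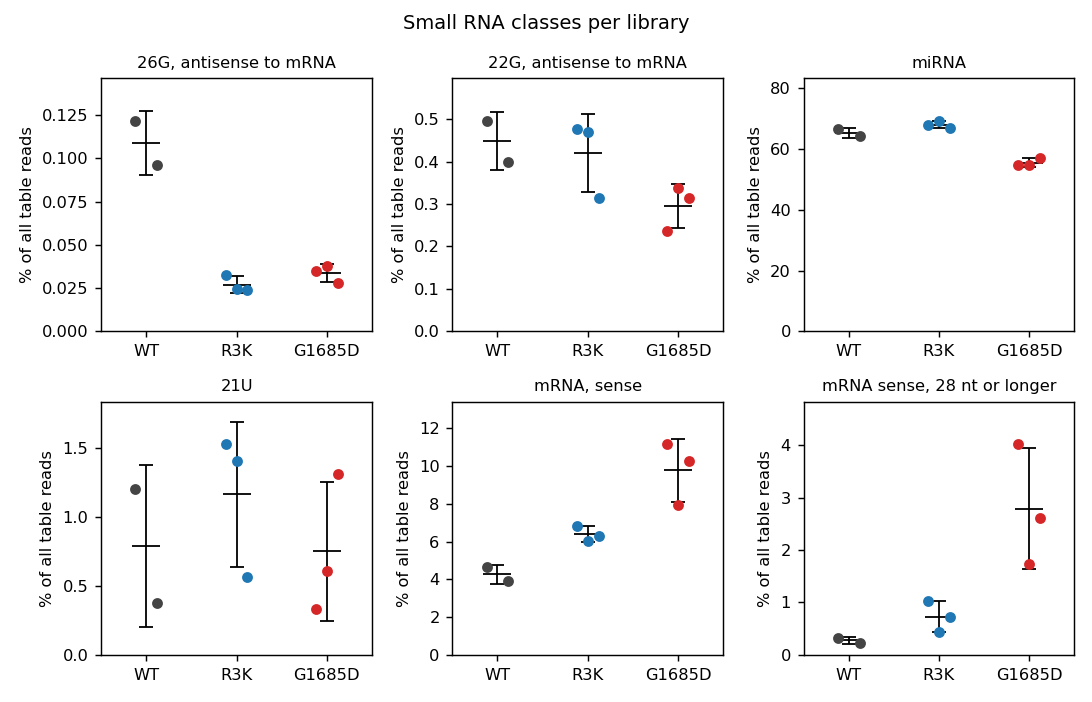
Share of all table reads (percent, linear axes from 0) in 6 small RNA classes for each library of WT, R3K and G1685D; points are libraries and bars are the mean ± SD. Antisense 26G reads lay at 0.109% in WT, 0.0270% in R3K and 0.0336% in G1685D.

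The comparison of R3K with WT asked which 26G siRNAs depended on the changed arginines of Dicer. In antisense 26G reads on mRNA, the F-box gene fbxa-3 (WBGene00020363, WBcel235 II 1818889 to 1820874) had 714 and 883 reads in WT and 0 in the 3 R3K libraries, at least 559.6-fold lower. The gene hpo-9 (WBGene00015463, V 7234922 to 7237130) had 125 ± 39.9 CPM in WT and 3 reads over R3K, a ratio of 0.000993 (95% counting interval 0.000205 to 0.00291). The classical ERGO-1 target K02E2.6 (WBGene00010507, V 20380561 to 20382036) fell from 30.4 ± 1.12 to 0.706 ± 0.0794 CPM, log2 -5.40 (SE 0.51, adjusted p = 8.46e-07). T05E12.8 (WBGene00045382, V 17069139 to 17069921) fell from 71.7 ± 0.0648 to 1.71 ± 0.605 CPM, log2 -5.39 (SE 0.66, adjusted p = 8.04e-06). Of 66 genes tested, 35 fell and 8 rose in R3K, with a median log2 of -2.73, or -2.39 with unread genes at their bound.

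Other 26G genes lower in R3K were Y37E3.30 (log2 -6.35, SE 0.61, adjusted p = 8.46e-07), T16A1.10 (log2 -7.46, SE 0.93, adjusted p = 9.08e-06) and F52G3.8 (log2 -3.69, SE 0.48, adjusted p = 1.33e-05). Y116F11A.1 was at 0 reads in R3K and at least 120.9-fold lower, and 2 reads in R3K gave F55C9.5 a ratio of 0.0052 (interval 0.000627 to 0.0189). F55C9.3 had 1 read in R3K, a ratio of 0.00186 (interval 4.7e-05 to 0.0104), and Y37E11B.2 fell by log2 -3.31 (SE 0.64, adjusted p = 0.000426). Genes with higher 26G reads included F23F1.4 (WBGene00017745, II 25374 to 28423), at 0 reads in WT and 24, 11 and 14 in R3K, at least 15.54-fold higher. The LIM homeobox gene lim-6 (WBGene00002988, X 1072452 to 1079452) rose from 0.17 ± 0.113 to 2.15 ± 0.85 CPM, log2 3.54 (SE 0.72, adjusted p = 0.000543). spc-2 rose by log2 2.85 (SE 0.74, adjusted p = 0.00337) and F13C5.1 by log2 2.29 (SE 0.81, adjusted p = 0.0237). T20B12.5 rose at least 8.56-fold, the titin gene ttn-1 at least 4.44-fold, and the Mediator gene let-19 by a ratio of 5.71 (interval 1.67 to 30.2). In ERGO-1 class 26G targets, 9 of 9 tested members fell (9 also adjusted over the list alone), with a median log2 of -5.40, or -4.51 with unread genes at their bound. Camera gave the list an adjusted p of 0.012, and adjusted p = 0.167 with an estimated correlation. The Piwi gene prg-1 (0.42, adjusted p = 0.631), hcp-1 (0.12, adjusted p = 0.926), klp-7 (-0.02, adjusted p = 0.979) and klp-18 (-0.72, adjusted p = 0.493) did not pass. These were the tested members of the small RNA pathway list (1) and the cyclin list (3), and fbxa-3 was that of the F-box list. No member of the other 9 mRNA lists was tested in 26G reads. dcr-1 was not tested there either.

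The 26G count rested on both WT libraries: without WT replicate 1 it was 21 genes and without WT replicate 2 it was 23, with fewer genes tested. TMM within the 26G table, which removes a change of the whole class, gave 28 higher and 22 lower genes, moved the median to -0.12 from -2.73 (mRNA 26G reads, R3K vs WT) and turned the sign of 3 of the 43 calls. Library sizes from 21U reads gave 4 higher and 35 lower genes. In the reported test 46 genes had an unadjusted p under 0.05, and 49 had R3K and WT libraries that did not overlap. Chance gives 20% with 2 against 3 only for genes admitted without regard to group. The count filter can admit a gene through the 2 WT libraries alone, and only 28 of the 43 calls were tested without WT replicate 1. The 20% is therefore no fair measure for these genes.

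The comparison of G1685D with WT asked the same of the RNase III part of Dicer. Of the 66 genes with 26G reads, 31 fell and 18 rose, with a median log2 of -1.52. In G1685D fbxa-3 kept 2.03 ± 0.875 of 69.3 ± 14 CPM, log2 -5.07 (SE 0.62, adjusted p = 3.79e-05), and hpo-9 kept 8.11 ± 2.65 CPM, log2 -3.95 (SE 0.69, adjusted p = 0.000234). K02E2.6 fell by log2 -3.57 (SE 0.47, adjusted p = 3.79e-05) and T05E12.8 by log2 -4.09 (SE 0.62, adjusted p = 7.54e-05). F23F1.4 was at least 50.01-fold higher, and lim-6 rose to 9.44 ± 1.89 CPM, log2 5.65 (SE 0.75, adjusted p = 3.79e-05).

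Further 26G genes lower in G1685D were Y116F11A.1 (log2 -4.34, SE 0.58, adjusted p = 4.56e-05), Y57G11C.36 (log2 -4.57, SE 0.63, adjusted p = 3.79e-05), Y57G11C.51 (log2 -2.94, SE 0.47, adjusted p = 0.000114) and C36A4.10 (log2 -3.42, SE 0.64, adjusted p = 0.000423). Y37E3.30 fell by log2 -3.94 (SE 0.54) and F52G3.8 by log2 -3.60 (SE 0.49), while Y37E11B.2 was at -0.95 (SE 0.61, adjusted p = 0.176). Higher were spc-2 (log2 5.58, SE 0.79, adjusted p = 4.14e-05), the kinesin gene klp-12 (log2 4.35, SE 0.71, adjusted p = 0.000142), F13C5.1 (log2 4.113, SE 0.83, adjusted p = 0.000672) and T09F5.2 (log2 4.27, SE 0.95, adjusted p = 0.00132). T20B12.5 was at least 13.9-fold and ttn-1 at least 26.1-fold higher. The ratio for let-19 was 31.1 (interval 10.1 to 155), and that for the peroxiredoxin gene prdx-2 was 102 (interval 34.3 to 498). Of the ERGO-1 class 26G targets 6 of 9 fell (8 adjusted over the list alone), with a median log2 of -2.67 and a camera adjusted p of 0.0325, and adjusted p = 0.231 with an estimated correlation. prg-1 rose by log2 2.12 (SE 0.75, adjusted p = 0.0196). In contrast hcp-1 (0.74, adjusted p = 0.431), klp-7 (-0.67, adjusted p = 0.471) and klp-18 (-1.33, adjusted p = 0.226) did not pass. Without WT replicate 1 the count was 27 genes and without WT replicate 2 it was 31. TMM within the table gave 21 higher and 21 lower genes and moved the median to -0.32 from -1.52 (mRNA 26G reads, G1685D vs WT), and total mapped reads moved it to -2.03.

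To ask whether the mutants differed from each other, R3K was set against G1685D. In 26G reads, 28 genes were lower and 0 higher in R3K (edgeR, 34 at an unadjusted p under 0.05, DESeq2 0 higher and 29 lower). Reads of fbxa-3 were at least 16.9-fold lower in R3K, and hpo-9 had a ratio of 0.0154 (interval 0.00313 to 0.0463). K02E2.6 was lower by log2 -1.83 (SE 0.48, adjusted p = 0.00729), and klp-12 by log2 -3.41 (SE 0.58, adjusted p = 0.000579). Of the ERGO-1 class 26G targets 5 of 9 were lower (5 adjusted over the list alone), with a median log2 of -2.36, or -1.83 with unread genes at their bound, and a camera adjusted p of 0.278. In 34 of the 66 genes the R3K and G1685D libraries did not overlap, where chance gives 10% for genes admitted without regard to group. The count was 16 with total mapped reads, with 21U reads and with TMM within the table (6 higher and 10 lower). The median log2 was -1.69 as reported (-1.57 with unread genes at their bound) and -1.09, -2.05 and -0.31 with these scalings (mRNA 26G reads, R3K vs G1685D).

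Both mutants shared 28 of the genes with lower and 8 of those with higher 26G reads, where independent lists would share 16.4 and 2.18, and 0 genes moved in opposite directions. Across these genes, which are not independent replicates, the log2 fold changes had r = 0.872, and simulated groups without changes, set against a shared simulated WT group, gave 0.536. The covariance was 13.5 against 0.400 in the simulation. For all antisense mRNA reads the mutants shared 101 higher and 39 lower genes (11.2 and 7.77 if independent), and 8 were opposite. Here r was 0.614 against 0.520 simulated, and the covariance 0.908 against 0.147. For miRNA they shared 10 lower and 0 higher entries (4.27 lower if independent). There r was 0.321 against 0.569 simulated, and the covariance 0.783 against 0.175. WT had 2 libraries and could not be divided between the mutants. In the simulation all 8 libraries, WT included, were drawn without changes between groups. Its values therefore show what a shared WT group gives alone, and the count filter was not applied again to the drawn counts. For miRNA r lay below its simulated value.

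**Figure D2:**
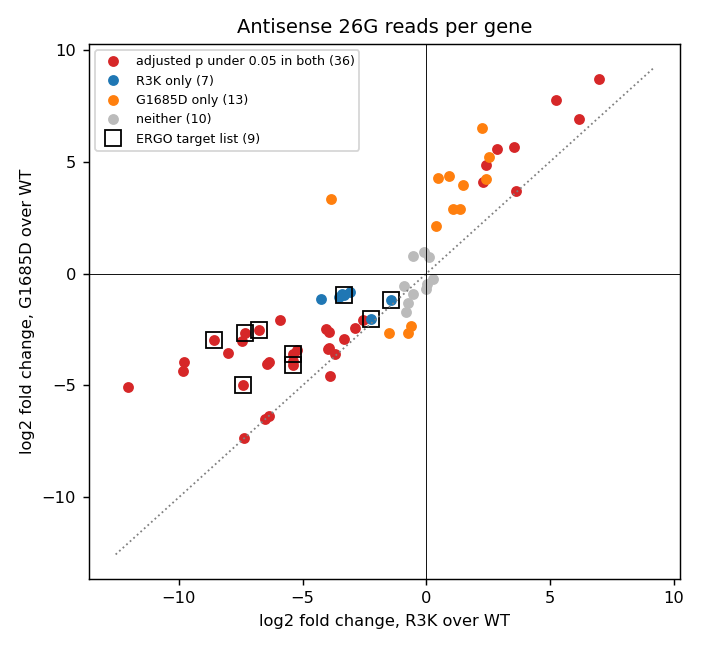
Log2 fold change of antisense 26G reads in R3K over WT (horizontal) and G1685D over WT (vertical) for 66 genes, each point 1 gene, coloured by whether the adjusted p was under 0.05 in both, 1 or neither contrast, with ERGO-1 class targets boxed and a dotted line of equal change. Of these genes 28 were lower and 8 higher in both mutants. Fitted folds of genes with all-zero groups depend on the prior count, so points beyond the printed bounds have no exact place.

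Among 6 noncoding RNAs tested for antisense 26G reads, 2 rose and 3 fell in R3K, and 2 rose and 2 fell in G1685D. C06A12.20 (WBGene00255703, IV 17438395 to 17439169) had 54.2 ± 16.1 CPM in WT and 0 reads in R3K, at least 437-fold lower, and fell by log2 -5.58 (SE 0.75, adjusted p = 1.55e-07) in G1685D. F31C3.15 (WBGene00198814, I 15063050 to 15063383) was at 0 in WT and at least 10.8-fold higher in R3K and 28.9-fold higher in G1685D. A noncoding transcript of bre-3 rose by log2 2.01 (SE 0.78, adjusted p = 0.0231) and 4.58 (SE 0.88, adjusted p = 2.55e-05). Without WT replicate 1 and without WT replicate 2 the R3K count was 1 and the G1685D count 2 (fewer genes were tested). Without R3K replicate 1 the R3K count was 3 (ncRNA 26G reads, R3K vs WT, and ncRNA 26G reads, G1685D vs WT).

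All antisense reads on mRNA were compared to find loci beyond the 26G class. In R3K, 103 genes rose and 83 fell of 4627 tested, with a median log2 of -0.17. F23F1.4 rose from 0.381 ± 0.285 to 22.7 ± 2.25 CPM, log2 5.82 (SE 0.52, adjusted p = 2.72e-08), and Y67D8C.2 (WBGene00022066, IV 3072297 to 3073916) from 2.07 ± 0.135 to 62.2 ± 8.42 CPM, log2 4.90 (SE 0.47, adjusted p = 9.07e-08). The touch receptor gene mec-2 (WBGene00003166, X 5567754 to 5590830) rose by log2 5.72 (SE 0.57, adjusted p = 1.45e-07). fbxa-3 fell from 83.1 ± 15.9 to 0.309 ± 0.272 CPM, log2 -7.93 (SE 0.50, adjusted p = 2.55e-10), and F43E2.6 (WBGene00018394, II 7366455 to 7368861) from 524 ± 106 to 11.2 ± 3.65 CPM, log2 -5.55 (SE 0.46, adjusted p = 1.1e-08).

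Other genes higher in R3K were F41G4.8 (log2 4.28), K06A9.1 (log2 4.24), Y73E7A.8 (log2 6.57, SE 0.71), the channel genes trpl-5 (log2 4.19) and twk-4 (log2 4.47, SE 0.52), lpr-7 (log2 4.05) and T11F8.4 (log2 4.46). Lower were hpo-9 (log2 -6.63, SE 0.50), Y37E3.30 (log2 -6.16, SE 0.43), T16A1.10 (log2 -5.54), T05E12.8 (log2 -5.15, SE 0.43), K02E2.6 (log2 -4.78, SE 0.36), W04B5.8 (log2 -4.35), C36A4.10 (log2 -4.19) and F52G3.8 (log2 -3.88). In ERGO-1 class 26G targets 12 of 14 fell (12 fell and 1 rose adjusted over the list alone), with a median log2 of -4.05, or -3.86 with bounded genes, and a camera adjusted p of 7.55e-22. The list had adjusted p = 0.00171 in camera with an estimated correlation. Of 8 collagen genes col-126 rose by log2 2.04 (SE 0.46, adjusted p = 0.00582) and 2 rose adjusted over the list alone, with a median log2 of 0.85. Collagen genes had a camera adjusted p of 0.000553, and adjusted p = 0.155 with an estimated correlation. On the genes called higher, reads of 28 nt or longer made up 15.98% of antisense reads in WT and 37.3% in R3K. On the genes called lower, 42.6% of those in WT were 26G reads.

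The other lists did not pass in R3K. None of 37 oocyte genes (camera adjusted p = 0.711), 39 meiosis genes (0.163), 17 histone genes (0.198), 7 heat shock genes (0.109) or 36 cyclin and cell division genes (0.108) was called by edgeR, over all genes or adjusted over the list alone. Among these were car-1 (-0.65, adjusted p = 0.445), lin-5 (-0.24, adjusted p = 0.829), the yolk receptor gene rme-2 (-0.19, adjusted p = 0.9), htp-1 (-0.52, adjusted p = 0.576) and hsp-60 (-0.85, adjusted p = 0.151). Of 70 small RNA pathway genes 1 fell (camera adjusted p = 0.108), with wago-4 at -0.62 (adjusted p = 0.517) and glh-4 at -0.55 (adjusted p = 0.59). Of 49 F-box and MATH genes 1 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.173), with a median log2 of 0.26 and a mean of -0.24. The pharynx myosin gene myo-1 rose by log2 1.79 (SE 0.48, adjusted p = 0.0283) among 6 body muscle genes (camera adjusted p = 0.174). None of 7 neuron genes passed over all genes and 2 rose adjusted over the list alone (camera adjusted p = 0.117). Among them flp-16 lay at 1.03 (adjusted p = 0.43) and unc-10 at 1.28 (adjusted p = 0.0771). None of 3 sperm genes and 2 gut genes passed over all genes, and 1 sperm gene fell adjusted over its list alone; ssp-19 had a ratio of 0.0732 (interval 0.00842 to 0.292, adjusted p = 0.0547). dcr-1 itself (WBGene00000939, III 8071967 to 8080281, minus strand) had 5.37 ± 0.649 CPM in WT, 4.97 ± 0.394 in R3K (log2 -0.11, SE 0.32, adjusted p = 0.942) and 4.79 ± 1.15 in G1685D (log2 -0.18, SE 0.34, adjusted p = 0.73).

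The R3K count was 104 without WT replicate 1 and 108 without WT replicate 2. With 21U reads as library size 31 genes rose and 84 fell, and the median log2 moved to -0.90 from -0.17 (mRNA all reads, R3K vs WT). Libraries of R3K and WT did not overlap in 1443 genes. Chance gives 20% only for genes admitted without regard to group, and the count filter can admit a gene through 1 group alone.

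In G1685D 503 genes rose and 433 fell, with a median log2 of -0.40. On the genes called higher, reads of 28 nt or longer made up 6.88% of antisense reads in WT and 23.9% in G1685D, and 22G reads 11.9% and 4.63%. Y67D8C.2 rose to 144 ± 20.8 CPM, log2 6.11 (SE 0.50, adjusted p = 6.57e-09), F23F1.4 to 66 ± 9.13 CPM, log2 7.36 (SE 0.54, adjusted p = 4.37e-09), and dpy-22, a Mediator gene, by log2 5.67 (SE 0.48, adjusted p = 8.02e-09). C37A5.11 (WBGene00077520, I 14171054 to 14173007) fell from 44.8 ± 5.27 to 0.562 ± 0.425 CPM, log2 -6.25 (SE 0.48, adjusted p = 4.37e-09), while it lay at 66.9 ± 2.97 CPM in R3K. fbxa-3 fell by log2 -4.38 (SE 0.40, adjusted p = 2.43e-08) and F43E2.6 by log2 -3.83 (SE 0.43).

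Further genes higher in G1685D were twk-4 (log2 6.69, SE 0.58), F41G4.8 (log2 5.94), C45G7.4 (log2 5.72), K06A9.1 (log2 5.58), Y54G2A.13 (log2 5.43), pifk-1 (log2 5.37) and Y37F4.6 (log2 5.34). Lower were T05E12.8 (log2 -4.17, SE 0.42), hpo-9 (log2 -3.84, SE 0.43), gba-3 (log2 -3.68, SE 0.38), Y37E3.30 (log2 -3.59), F52G3.8 (log2 -3.13) and K02E2.6 (log2 -1.71, SE 0.31). Also lower were C34F6.10 (log2 -5.55) and rfc-1 (log2 -4.93), whose antisense reads tracked those of mir-39 and mir-36. In all, 10 mRNA entries that tracked a miRNA held 92.7% of antisense mRNA reads, among them srz-67 with mir-1 and srt-17 with mir-71. In G1685D 1 of these was called higher and 3 lower. Of 8 collagen genes 7 rose (7 adjusted over the list alone), with a median log2 of 2.49 and a camera adjusted p of 2.61e-07. The collagen list had adjusted p = 0.0524 in camera with an estimated correlation. dpy-2 rose from 281 ± 103.8 to 1928 ± 460 CPM (log2 2.78, SE 0.53, adjusted p = 0.000561). With it col-153 (log2 3.18, SE 0.50, adjusted p = 5.49e-05) and col-126 (log2 4.395, SE 0.48, adjusted p = 2.24e-07) rose. Of the ERGO-1 class 26G targets 8 of 14 fell (8 adjusted over the list alone), with a median log2 of -1.64 and a camera adjusted p of 0.00113. This list had adjusted p = 0.0524 in camera with an estimated correlation. Of 49 F-box and MATH genes 11 rose and 2 fell (11 and 2 adjusted over the list alone, median log2 0.52, camera adjusted p = 0.00677, and adjusted p = 0.0524 with an estimated correlation).

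Germ line lists lay lower in antisense reads of G1685D, against a median log2 of -0.40 for all genes. Of 37 oocyte genes 8 fell (8 adjusted over the list alone), with a median of -0.80 and a camera adjusted p of 0.009. Oocyte genes had adjusted p = 0.316 in camera with an estimated correlation. car-1 fell by log2 -1.003 (SE 0.32, adjusted p = 0.0286) and lin-5 by log2 -1.01 (SE 0.30, adjusted p = 0.0201), and rme-2 was at -0.43 (adjusted p = 0.398). Of 39 meiosis genes 4 fell (0 adjusted over the list alone with edgeR), with a median of -0.79 and a camera adjusted p of 0.00992. Meiosis genes had adjusted p = 0.315 in camera with an estimated correlation. htp-1 was 1 of the 4 (log2 -0.92, SE 0.32, adjusted p = 0.041) and chk-2 was at -0.64 (adjusted p = 0.172). Of 70 small RNA pathway genes 3 rose and 18 fell (3 and 20 adjusted over the list alone, camera adjusted p = 0.0278, and adjusted p = 0.402 with an estimated correlation). Those lower included the Argonaute gene wago-4 (log2 -1.19, SE 0.34, adjusted p = 0.0154) and glh-4 (log2 -1.02, SE 0.34, adjusted p = 0.038). Of 36 cyclin and cell division genes 14 fell (16 adjusted over the list alone), with a median of -0.92 and a camera adjusted p of 0.000274. Cyclin and cell division genes had adjusted p = 0.315 in camera with an estimated correlation. klp-18 fell by log2 -1.04 (SE 0.36, adjusted p = 0.0443). The remaining lists did not pass: 1 of 17 histone genes rose (camera adjusted p = 0.202), 2 of 6 muscle genes rose (2 and 1 lower adjusted over the list alone, 0.27) and 3 of 7 neuron genes rose (4 and 1 lower adjusted over the list alone, 0.0783). Also 3 of 7 heat shock genes fell (4 adjusted over the list alone, 0.165), and none of 3 sperm and 2 gut genes was called, with 1 sperm gene higher adjusted over its list alone. Among these myo-1 rose by log2 3.27 (SE 0.47, adjusted p = 1.73e-05), unc-15, the paramyosin gene, by log2 2.93 (SE 0.53, adjusted p = 0.000284) and flp-16 by log2 1.60 (SE 0.49, adjusted p = 0.024). The chaperone gene hsp-1 fell by log2 -1.23 (SE 0.33, adjusted p = 0.0116).

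The direction of the whole table followed the scaling: 307 rose and 1227 fell with total mapped reads, 141 rose and 65 fell with 21U reads, 628 rose and 179 fell with TMM within the table, and 502 rose and 139 fell with DESeq2. The median log2 moved from -0.40 to -0.90, -0.90, -0.07 and -0.23 with these scalings (mRNA all reads, G1685D vs WT). Without WT replicate 2 the count was 371, with 298 higher and 73 lower, so most of the lower calls, on which the counts of the germ line lists rest, ended there.

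Between the mutants 132 genes were higher and 389 lower in R3K than in G1685D. C37A5.11 was higher in R3K by log2 6.82 (SE 0.47, adjusted p = 1.69e-09) and gba-3 by log2 4.01 (SE 0.36, adjusted p = 1.36e-07), and bbs-5 was lower by log2 -7.41 (SE 0.62, adjusted p = 8.43e-08). Of the ERGO-1 class 26G targets 2 were higher and 10 lower (2 and 11 adjusted over the list alone, median log2 -2.42, camera adjusted p = 1.87e-06, and adjusted p = 0.0325 with an estimated correlation). Collagen genes were lower in 6 of 8 (6 adjusted over the list alone, median -1.89, camera adjusted p = 2.11e-05, and adjusted p = 0.0551 with an estimated correlation). F-box and MATH genes were lower in 6 and higher in 1 of 49 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00448, and adjusted p = 0.0551 with an estimated correlation). Oocyte genes were higher in 3 of 37 (3 adjusted over the list alone, median 0.53, camera adjusted p = 0.00186, and adjusted p = 0.391 with an estimated correlation). Cyclin and cell division genes were higher in 4 of 36 (6 adjusted over the list alone, median 0.54, camera adjusted p = 0.000954, and adjusted p = 0.435 with an estimated correlation). Of 39 meiosis genes none was called by edgeR, while camera gave an adjusted p of 0.0429, and adjusted p = 0.435 with an estimated correlation. Small RNA pathway (camera adjusted p = 0.152), histone (0.764), muscle (0.702), neuron (0.499) and heat shock genes (0.702) did not pass as lists. The split was 723 higher and 228 lower with total mapped reads, 8 and 184 with 21U reads and 57 and 396 with DESeq2. The median log2 was 0.16 as reported and 0.69, -0.06 and 0.04 with these (mRNA all reads, R3K vs G1685D). Without R3K replicate 1 the count was 335 and without R3K replicate 2 it was 309.

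Antisense 22G reads were compared to follow the step downstream of 26G reads. This table was chosen after seeing the data. In R3K 3 of 1314 genes rose and 7 fell. lim-6, F23F1.4 and K06A9.1 rose. C04A11.1, E01G4.5 (log2 -3.96), K02E2.6, fbxa-3, W04B5.8, Y37E11B.2 (log2 -2.81) and Y37E3.30 fell. Of 7 ERGO-1 class 26G targets 3 fell (4 fell and 1 rose adjusted over the list alone), with a median log2 of -2.81, or -1.95 with bounded genes, and a camera adjusted p of 0.000145. The list had adjusted p = 0.238 in camera with an estimated correlation. In G1685D 89 genes rose and 79 fell. Of 29 cyclin and cell division genes 8 fell (11 adjusted over the list alone, camera adjusted p = 0.0235, and adjusted p = 0.521 with an estimated correlation). R3K had 38 higher and 48 lower genes than G1685D. In G1685D the split was 37 and 302 with total mapped reads, 6 and 2 with 21U reads, 154 and 25 with TMM within the table and 90 and 16 with DESeq2. The count was 51 without WT replicate 2 and 96 without G1685D replicate 3 (mRNA 22G reads, G1685D vs WT). Between the mutants the split was 166 and 26 with total mapped reads, 3 and 15 with 21U reads, 36 and 79 with TMM within the table and 12 and 42 with DESeq2. The count between mutants was 48, 35 and 46 without R3K replicates 1, 2 and 3 and 53, 51 and 57 without G1685D replicates 1, 2 and 3 (mRNA 22G reads, R3K vs G1685D).

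Mature miRNAs were compared because Dicer also releases them from their precursors. In G1685D the mir-35 family, which acts in embryos, fell: mir-35-3p (WBGene00003263, II 11537608 to 11537704) had 463819 and 525102 reads in WT and 1568, 6809 and 1507 in G1685D, log2 -5.92 (SE 0.54, adjusted p = 1.1e-12). mir-37-3p fell by log2 -5.94 (SE 0.52, adjusted p = 5.43e-13), and mir-39-major from 14026 ± 308 to 288 ± 75 CPM, log2 -5.61 (SE 0.48, adjusted p = 3.49e-13). In the let-7 family, which times larval development, 9 of 13 entries rose (camera adjusted p = 3.36e-06, and adjusted p = 0.483 with an estimated correlation). Entries of both arms were counted. Among them mir-241-3p, the arm with fewer reads (7513 over all libraries against 70085 for 5p), rose from 35.3 ± 7.9 to 412 ± 122 CPM, log2 3.54 (SE 0.54, adjusted p = 3.65e-07). Of 236 entries tested 31 rose and 72 fell in G1685D, with a median log2 of -0.37.

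All 16 tested members of the mir-35 family fell (16 adjusted over the list alone), with a median log2 of -5.03 and a camera adjusted p of 1.54e-10. The family had adjusted p = 0.315 in camera with an estimated correlation. With fry the adjusted p of the family was 0.000261. Among them were mir-40-5p (log2 -6.62), mir-40-3p (log2 -5.92), mir-39-minor (log2 -5.89), mir-36-5p (log2 -5.19) and mir-36-3p (log2 -4.88). Outside the family mir-1829.2-3p (log2 -5.88, SE 0.59, adjusted p = 1.08e-11) and mir-51-3p (log2 -5.71) fell. The 13 let-7 family entries had a median of 1.33, and 10 rose adjusted over the list alone. The higher entries included let-7-major (log2 1.53, SE 0.47, adjusted p = 0.00708), mir-48-5p (log2 1.33, SE 0.44, adjusted p = 0.0124), mir-84-5p (log2 1.15, SE 0.45, adjusted p = 0.0352) and mir-795-5p (log2 2.25). The 3 lin-4 family entries rose: lin-4-5p by log2 1.51 (SE 0.47, adjusted p = 0.00755), mir-237-5p by log2 1.45 (SE 0.47, adjusted p = 0.0103) and mir-237-3p by log2 1.49 (adjusted p = 0.0203). Also higher were mir-2214-5p (log2 3.32), mir-58.1-5p (log2 2.38, SE 0.50), mir-230-minor (log2 2.00), mir-228-3p (log2 1.97), mir-71-3p (log2 1.91), mir-245-3p (log2 1.71) and mir-248 (log2 1.60).

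Of the other miRNA lists in G1685D, muscle and neuron miRNAs rose in 3 of 10 entries (median 0.79, camera adjusted p = 0.0142, and adjusted p = 0.691 with an estimated correlation). In this list mir-1-3p lay at 0.79 (adjusted p = 0.158) and mir-790-5p at 1.02 (adjusted p = 0.105). The mir-44 family fell in 3 of 6 (0.34), including mir-61-3p (log2 -2.56, SE 0.43, adjusted p = 2.53e-06). The mir-2 family fell in 3 of 6 (0.161), including mir-250-3p (log2 -4.36, SE 0.51) and mir-250-5p (log2 -4.38). The mir-51 family fell in 3 of 10 (0.759), with mir-51-5p at log2 -1.74 (SE 0.43, adjusted p = 0.000887). The mir-72 family fell in 3 of 6 (0.477), with mir-74-5p at log2 -1.38 (adjusted p = 0.0123), and the mir-64 family in 1 of 7 (0.682). The mir-58 family rose in 2 and fell in 3 of 9 (0.477), with mir-80-3p at log2 1.32 (SE 0.46, adjusted p = 0.017). Of 3 mirtrons 2 fell, mir-1018 (log2 -3.30, SE 0.64, adjusted p = 3.31e-05) and mir-1020-3p (log2 -1.82, adjusted p = 0.00404), while mir-62 was at -0.59 (adjusted p = 0.38). The 5p arms rose in 9 and fell in 29 of 77 (0.477), and the 3p arms rose in 13 and fell in 28 of 84 (0.759). The split was 17 higher and 100 lower with total mapped reads, with the median at -0.92, and 3 and 60 with 21U reads, with the median at -0.86 (miRNA, G1685D vs WT). The 16 mir-35 family members remained lower under every scaling tried. The let-7 family had 1 of 13 entries higher with 21U reads as library size, 5 with total mapped reads, 3 with the replicate block, 2 without WT replicate 1 and 3 without WT replicate 2. Of the 20 entries named by rule, 8 did not pass with 21U reads and 3 did not without WT replicate 1. Without WT replicate 2 the count was 66, and let-7-major and mir-245-3p did not pass.

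In R3K 14 entries fell and 0 rose (edgeR, 41 at an unadjusted p under 0.05; DESeq2 1 higher and 13 lower). mir-4813-5p fell from 47.2 ± 19.9 to 6.62 ± 5.14 CPM, log2 -2.84 (SE 0.63, adjusted p = 0.00237). mir-86-3p fell from 121 ± 25.4 to 30.2 ± 4.1 CPM, log2 -2.01 (SE 0.45, adjusted p = 0.00237), and mir-44-5p from 431 ± 208 to 125 ± 53.2 CPM, log2 -1.78 (SE 0.47, adjusted p = 0.0131). mir-788-minor (log2 -2.09, SE 0.50), mir-49-5p (log2 -1.61, SE 0.46), mir-231-5p (log2 -1.53, SE 0.46) and the mirtron mir-1018 (log2 -1.94, SE 0.57, adjusted p = 0.0253) fell as well. The mir-35 family had 0 calls in 16 entries (camera adjusted p = 0.987), with mir-35-3p at 0.58 (SE 0.49, adjusted p = 0.592) and mir-39-major at 0.70 (adjusted p = 0.466). The let-7 family had 0 in 13, with a median of 0.49, a camera adjusted p of 0.0107, and adjusted p = 0.884 with an estimated correlation. The 5p arms fell in 7 of 77 (11 adjusted over the list alone, 0.576), the 3p arms in 2 of 84 (0.576), the mir-44 family in 1 of 6 (0.576) and mirtrons in 1 of 3. The lin-4 family had 0 calls in 3, mir-51 0 in 10 (0.681), mir-58 0 in 9 (0.576), mir-64 0 in 7 (0.681), mir-2 0 in 6 (0.681), and mir-72 0 in 6 (0.576). Muscle and neuron miRNAs had 0 in 10 (0.481), with mir-1-3p at -0.46 (SE 0.43, adjusted p = 0.623) and mir-71-5p at -0.05 (adjusted p = 0.935). Of these calls 4 remained without R3K replicate 1, 5 without R3K replicate 2 and 13 without R3K replicate 3, where the count of all calls was 21. Only 10 of the 14 were tested without a WT library, and of these 5 remained without WT replicate 1 and 0 without WT replicate 2. TMM within the table gave 3 higher and 15 lower entries. With 21U reads as library size the median moved to -0.85 from -0.16 (miRNA, R3K vs WT).

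Between the mutants 60 miRNA entries were higher and 37 lower in R3K. mir-39-major was higher by log2 6.31 (SE 0.48, adjusted p = 6.17e-15), and the mir-35 family was higher in 15 of 16 entries (median 5.22, camera adjusted p = 3.65e-11, and adjusted p = 0.28 with an estimated correlation). The let-7 family was lower in 5 of 13 (6 adjusted over the list alone, median -0.99, camera adjusted p = 0.00366, and adjusted p = 0.833 with an estimated correlation), with mir-241-3p at log2 -3.06 (SE 0.44, adjusted p = 1.29e-07). Muscle and neuron miRNAs were lower in 5 of 10 (8 adjusted over the list alone, median -1.40, camera adjusted p = 0.000839, and adjusted p = 0.612 with an estimated correlation). The split was 86 and 22 with total mapped reads and 34 and 11 with 21U reads, with the median log2 at 0.13 as reported, 0.69 and -0.04 (miRNA, R3K vs G1685D).

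**Figure D3:**
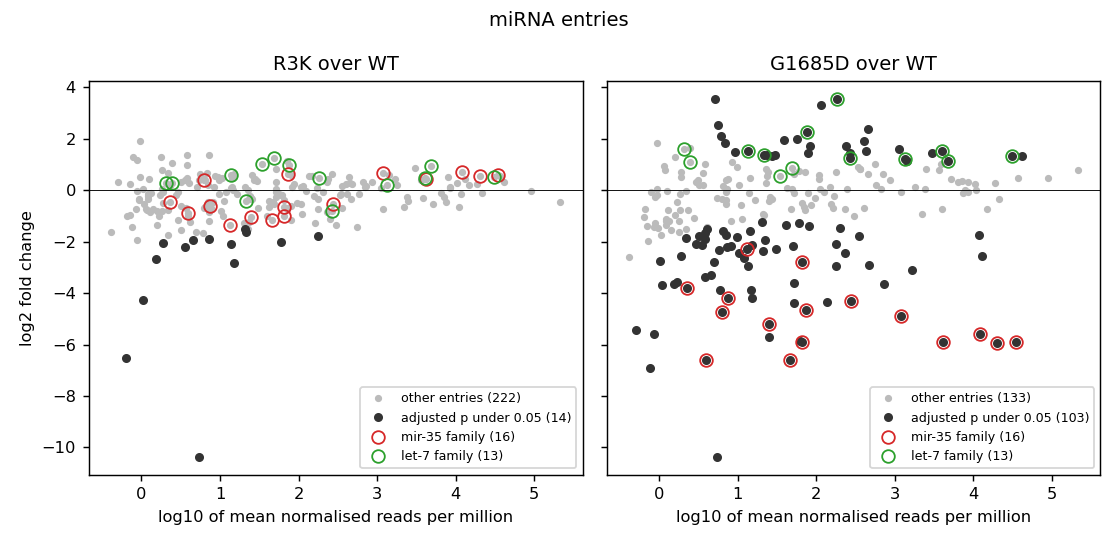
Log2 fold change over WT of 236 miRNA entries against the log10 of their mean normalised reads (CPM), for R3K (left) and G1685D (right); each point is 1 entry, dark where the adjusted p was under 0.05, with the mir-35 and let-7 families ringed. The 16 entries of the mir-35 family were called lower in G1685D and none in R3K. Fitted folds of entries with all-zero groups depend on the prior count.

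The use of both miRNA arms was compared in 57 miRNAs, since Dicer cuts release both. G1685D had 5 miRNAs shifted toward the 5p arm and 9 toward the 3p arm against WT, among them mir-51 (log2 3.77, SE 0.53, adjusted p = 0.00261) and mir-58.1 (log2 2.00) toward 5p and mir-44 (log2 -2.92), mir-241 (log2 -2.26) and mir-228 (log2 -2.06) toward 3p. R3K had 0 against WT (limma, 8 at an unadjusted p under 0.05), and 15 miRNAs differed between the mutants. The median log2 of 5p over 3p reads was -1.01 ± 0.31 in WT, -1.46 ± 0.23 in R3K and -1.58 ± 0.58 in G1685D (exact permutation p = 0.3 for each mutant against WT and 0.8 between them). Without WT replicate 1 and without WT replicate 2 the G1685D count was 5 and 0, and without R3K replicates 1, 2 and 3 the count between mutants was 7, 8 and 7 (5p arm against 3p arm of miRNA, G1685D vs WT, and 5p arm against 3p arm of miRNA, R3K vs G1685D).

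Sense reads on mRNA were compared after seeing the data. At the 28 genes with 26G reads lower in both mutants, sense reads of 18 to 20 nt made up 76.4% ± 0.655 of all sense reads in WT (SD, n = 2), 15.4% ± 0.873 in R3K (n = 3) and 11.06% ± 9.57 in G1685D (n = 3), or 998.6 ± 331, 4.14 ± 1.45 and 7.96 ± 7.83 CPM. The G1685D libraries differed, at 4.32%, 22.01% and 6.85% (3.72, 16.99 and 3.17 CPM), so the G1685D means rest largely on replicate 2. On other genes they made up 5.04%, 7.66% and 4.66%. T05E12.8 had 2151 and 2450 sense reads in WT, and its sense reads fell by log2 -7.33 (SE 0.78) in R3K and -6.31 (SE 0.75) in G1685D. Of 12 ERGO-1 class 26G targets 12 fell in R3K (camera adjusted p = 1.61e-47, and adjusted p = 0.00177 with an estimated correlation) and 9 in G1685D (adjusted p = 0.0046 with an estimated correlation). Of 46 sperm genes 39 rose in R3K, with a median log2 of 4.43, or 2.66 with bounded genes, and a camera adjusted p of 0.00778. The R3K list had adjusted p = 0.565 in camera with an estimated correlation. In G1685D 46 rose, with a median of 7.06, or 5.54 with bounded genes, and a camera adjusted p of 3.61e-20. The G1685D list had adjusted p = 0.123 in camera with an estimated correlation. These 46 genes together held 49 and 59 reads in the WT libraries, so most passed the count filter through mutant reads, which favours a rise. The major sperm protein gene msp-36 rose by log2 4.65 (SE 0.65, adjusted p = 3.75e-07) and 7.32 (SE 0.73, adjusted p = 1.01e-10). Over 3634 genes 2250 rose and 92 fell in R3K, with a median log2 of 1.99. In G1685D 2104 rose and 80 fell, with a median of 1.80. TMM within the table gave 420 higher and 432 lower in R3K and 512 and 216 in G1685D, with medians of 0.26 and 0.15 (mRNA sense reads, R3K vs WT, and mRNA sense reads, G1685D vs WT). With 21U reads as library size 482 rose and 85 fell in R3K and 682 and 69 in G1685D. R3K had 173 higher and 648 lower genes than G1685D, but 788 higher and 448 lower with total mapped reads and 8 and 394 with 21U reads.

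**Figure D4:**
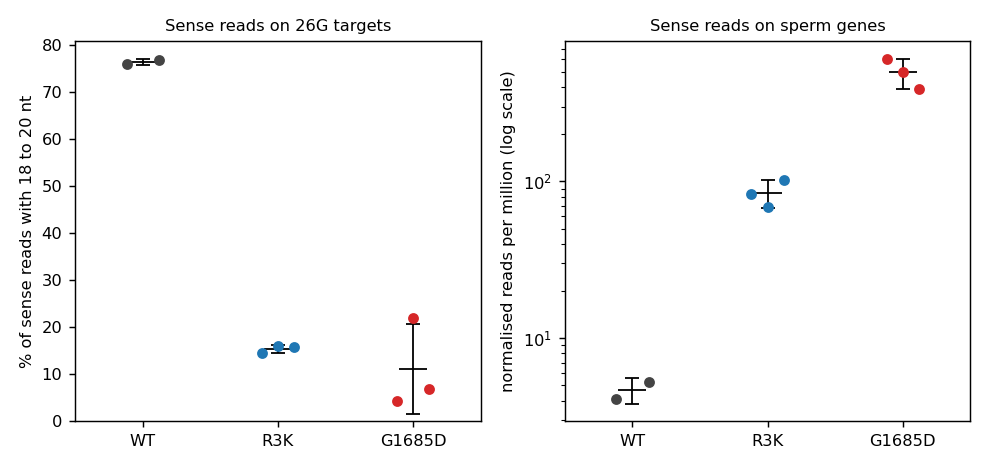
Left, percent of sense reads with 18 to 20 nt on 28 genes with lower 26G reads in both mutants; right, normalised sense reads (CPM) on 46 sperm genes (log axis). Points are libraries of WT, R3K and G1685D and bars the mean ± SD; the left values lay at 76.4% in WT, 15.4% in R3K and 11.06% in G1685D.

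Reads of piRNAs and transposons were compared as further classes, and the transposon reads were not split by length. Of 1284 piRNAs 0 passed in R3K (edgeR, 6 at an unadjusted p under 0.05; DESeq2 0). In G1685D 0 passed (edgeR, 108 at an unadjusted p under 0.05; DESeq2 41 higher and 1 lower). The edgeR count in G1685D was 17 without WT replicate 1 and 15 without G1685D replicate 3 (piRNA 21U reads, G1685D vs WT). Of 66 transposon entries 3 fell in R3K, F49C5.8, T16A1.9 and T25G12.8, each at 0 reads in its 3 libraries against 62, 544 and 66 in WT. All 3 also fell in G1685D, T16A1.9 by log2 -3.25 (SE 0.48, adjusted p = 0.000173) and T25G12.8 by log2 -2.91 (SE 0.57, adjusted p = 0.000742). F49C5.8 had 1 read in G1685D, a ratio of 0.0269 to WT (interval 0.00067 to 0.155). In G1685D 28 rose and 8 fell, with B0303.5 up from 7.37 ± 1.12 to 18.7 ± 4.12 CPM (log2 1.34, SE 0.31, adjusted p = 0.0018) and T27C5.9 from 18.4 ± 0.604 to 34.1 ± 7.75 CPM (log2 0.89, SE 0.35, adjusted p = 0.0419). That split was 7 and 9 with total mapped reads and 5 and 7 with 21U reads, and under both settings B0303.5 and T27C5.9 did not pass. The median log2 was 0.84 as reported, 0.35 and 0.42 (transposon reads, G1685D vs WT). Without WT replicate 1 and without WT replicate 2 the count was 19 and 22 in G1685D, and 1 and 1 in R3K.

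In the authors' deposited comparisons, 65 of 123 features of the ERGO class of 26G reads and 311 of the ALG class had a fold change. Of the 65, 26 were lower at an adjusted p under 0.05 in R3K and 28 in G1685D, against 1 and 1 of the 311. In each of these classes 0 features passed as higher. The authors' table gave K02E2.6 a log2 of -5.88 in R3K and -4.05 in G1685D, and Y116F11A.1 -9.59 and -4.99. Of the 20 ERGO class genes also tested here for 26G reads, 19 had a fold change in the authors' tables. The authors' sign and the sign here were equal in all 19 for each mutant. The gene without a fold change, ttn-1, had a mean signal of 0 in the authors' tables. Its 26G reads were called higher here in both mutants. For miRNA the authors' table listed 1 higher and 20 lower of 343 in R3K, and 9 and 76 in G1685D. For CSR class 22G reads it listed 0 features of 3545 in R3K and 1 higher and 96 lower in G1685D. Other classes went the other way. Unclassified siRNAs had 99 higher and 25 lower of 9218 in R3K, and 836 and 55 in G1685D. In G1685D unclassified 22G features had 136 higher and 7 lower, WAGO class 22G 21 and 12, and piRNAs 56 and 13. Of 23 rRNA features 5 were higher in R3K and 22 in G1685D, with 0 lower.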

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

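Of the tests in this part, those on scaling, on 22G reads, on wild-type material in G1685D, on 21U reads as a measure of the germ line and on the sum of sperm gene reads were chosen after the result was seen, as were the splits for 22G reads and for sense reads. The planned ones were those on oocyte genes, on 26G reads of sperm genes and on the remaining splits.

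Sense reads lie outside the planned comparisons, and several of their shares were higher in the mutants than in WT. The share of sense 26G reads on mRNA was 2.74 times WT in R3K and 2.605 times in G1685D, and that of all sense mRNA reads was 1.499 and 2.29 times WT (exact permutation p = 0.1 for each). Reads of 23 nt alone made up 64.5% of sense mRNA reads in WT, 52.9% in R3K and 47.6% in G1685D. Whether sense reads on mRNA entries tracked miRNA entries was not tested. Sense mRNA reads of 28 nt or longer were at 2.63 and 10.05 times WT, and sense reads on noncoding RNA at 1.41 and 1.74 times (exact permutation p = 0.2 for each). Sense reads on the 46 tested sperm genes were at 4.08 and 5.29 CPM in WT, at 83.0, 68.9 and 102.7 CPM in R3K and at 606, 494 and 389.6 CPM in G1685D, 18.1 and 106 times the WT level. Most of these genes entered the test through reads of the mutants, which favours a rise.

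The first pattern is the fall of antisense 26G reads in both mutants, with some reads left in G1685D. Over 4 other scalings and both mutants at least 21 genes remained called lower, against 35 and 31 reported, which argues against library size or normalization as the whole cause. The lowest mutant library kept 0.529 of the WT share of 22G reads, where a general loss of antisense siRNA reads as deep as that of 26G reads in G1685D, the mutant of that library, would bring it near 0.308. The 28 genes lower in both mutants kept a median of 8.16% of WT in G1685D (quartiles 4.73% and 13.8%), while the mir-35 family kept 1.78% and mir-8199 had 0 reads (upper limit 1.01% of WT), which argues against wild-type animals or RNA mixed into those libraries. A smaller effect of G1685D than of R3K on the same siRNAs may remain as a biological hypothesis, found and tested on the same data.

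The second pattern is the fall of the mir-35 family in G1685D. All 16 tested members remained called lower under the 4 other scalings, which argues against library size or normalization. The lowest G1685D library kept 0.422 of the WT mean share of 21U reads and the group mean was 0.951 of WT, which argues against a germ line reduced by as much as these miRNAs; the bound on the single library was added after the values were seen. Fewer oocytes could not be told apart: sense reads of 39 oocyte genes lay at a median log2 of -0.91 in G1685D against R3K relative to all genes (quartiles -1.25 and -0.24), between the limits of -0.5 and -1 set for the test, and the mRNA fragments may not follow cell number. A direct effect of the changed RNase III part on these precursors, or a change in embryos carried by the animals, was not tested.

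The third pattern is the rise of sperm gene sense reads in both mutants. The log2 ratio of the list sum exceeded the median of all tested genes by 2.19 in R3K and 4.93 in G1685D. The 46 genes together held only 49 and 59 reads in the WT libraries, so most entered the test through reads of the mutants. Such entry favours a rise, so the excess cannot decide whether more mRNA fragments of every gene were the whole cause. The list sum was chosen after the medians with bounded genes were seen. Those medians exceeded the median of all genes by 0.67 in R3K and 3.74 in G1685D. A parallel rise of sperm-class 26G reads could not be told apart, since antisense 26G reads on the list were 0.462 of WT in R3K and 1.46 in G1685D on only 24 reads. More sperm or less breakdown of sperm mRNA in the mutants may each be an open biological explanation, and neither was tested.

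For the comparison of both mutants, the 6 mutant libraries allow 10 splits, too few for a share under 0.05. The real split was 1 of 10 with as many calls for 26G reads (28 genes, highest other 0), for all antisense mRNA reads (521, highest other 0), for miRNA (97, highest other 0), for 22G reads (86, highest other 0), for sense reads (821, highest other 0), for arms (15, highest other 1) and for mRNA lists (6, highest other 4). For miRNA lists 5 of 10 splits gave as many (3, highest other 4), and for 26G lists 10 of 10 did (0, highest other 0).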

How the results depend on the processing

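The alternatives with isoforms summed, both strands summed, the 21U covariate, 21 to 23 nt reads, and every alternative for 22G and sense reads were chosen after seeing the data. Of the named genes, 79 results over all settings no longer passed and none turned its direction. Among all called genes some did. TMM within the table turned the sign of 3 of 43 calls for 26G reads in R3K vs WT, and for sense reads of 269 of 2342 calls in R3K vs WT and 277 of 2184 in G1685D vs WT. Both strands summed turned 23 of 936 calls for mRNA all reads in G1685D vs WT, 4 of 186 in R3K vs WT and 4 of 521 in R3K vs G1685D. Without G1685D replicate 1, 1 call turned in mRNA all reads in each contrast with G1685D and 1 in sense reads, G1685D vs WT. The balance of higher and lower genes also turned with scaling. For 26G reads in R3K vs WT it went from 8 higher and 35 lower to 28 and 22 with TMM within the table, and for mRNA all reads in R3K vs G1685D from 132 and 389 to 723 and 228 with total mapped reads. Counts without a WT library leave 1 WT library, assumed to vary like the other groups. In the 26G table the self-test recovered 37.5% of 4-fold changes. Libraries with the same number did not pair: R3K and G1685D libraries of equal number correlated at -0.16, -0.0913 and -0.367 after removal of group means, and not every sample correlated best with its own number, so a call lost with the replicate block is not called a weaker effect. Where no reason is given, the cause was not tested.

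For mRNA 26G reads, R3K vs G1685D, the count of 28 became 16 with total mapped reads, 16 with 21U reads, 16 with TMM within the table, 13 with no filter, 18 with the replicate block and 47 with both strands summed. For mRNA all reads, G1685D vs WT, 936 became 1534 with total mapped reads, 206 with 21U reads, 608 with the block and 1659 with both strands. For mRNA all reads, R3K vs G1685D, 521 became 951, 192 and 1526 with total mapped reads, 21U reads and both strands, and for mRNA all reads, R3K vs WT, 186 became 115 with 21U reads and 556 with both strands.

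For miRNA, R3K vs WT, the count of 14 became 28 with total mapped reads, 5 with 21U reads, 8 with the block, 7 with the 21U covariate and 39 with both strands. With 21U reads, miRNA, G1685D vs WT went from 103 to 63 and miRNA, R3K vs G1685D from 97 to 45. For piRNA 21U reads, G1685D vs WT, DESeq2 gave 42 against 0. For ncRNA 26G reads, R3K vs WT, 5 became 3 with 21U reads and 3 with the block. For transposon reads, G1685D vs WT, 36 became 16 with total mapped reads and 12 with 21U reads, and for transposon reads, R3K vs WT, 3 became 5 with both strands. For the 5p arm against 3p arm of miRNA, R3K vs WT, 0 became 3 with arms of at least 100 reads.

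For mRNA 22G reads, G1685D vs WT, 168 became 339 with total mapped reads, 8 with 21U reads, 79 with no filter, 100 with the block, 106 with DESeq2 and 428 with 21 to 23 nt reads. For mRNA 22G reads, R3K vs G1685D, 86 became 192, 18, 57, 133, 54 and 184 with total mapped reads, 21U reads, the block, the 21U covariate, DESeq2 and 21 to 23 nt reads. For mRNA 22G reads, R3K vs WT, 10 became 31 with 21 to 23 nt reads. For mRNA sense reads, R3K vs WT, 2342 became 567 with 21U reads and 852 with TMM within the table. For mRNA sense reads, G1685D vs WT, 2184 became 1408 with total mapped reads, 751 with 21U reads and 728 with TMM within the table, and for mRNA sense reads, R3K vs G1685D, 821 became 1236 with total mapped reads and, with 21U reads, 8 higher and 394 lower.

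Relative to 21U reads, the log2 ratios of class totals per library were as follows. For R3K vs WT they were -0.68 for miRNA, -0.90 for mRNA, -1.63 for 26G on mRNA, -2.73 for its antisense reads, -0.88 for antisense 22G, 0.14 for ncRNA and -0.50 for transposons. For R3K vs G1685D they were -0.49 for miRNA, -1.28 for mRNA, -0.99 for 26G on mRNA, -1.22 for its antisense reads, -0.32 for antisense 22G, -1.82 for ncRNA and -1.25 for transposons, and for G1685D vs WT -0.19 for miRNA. With listed entries summed in place of the total line, class totals per library, transposon, G1685D vs WT went from 0.63 to 0.27.

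Leaving out each library in turn gave ranges, lowest to highest. mRNA 26G reads ranged from 21 to 43 in R3K vs WT and from 27 to 50 in G1685D vs WT. mRNA all reads ranged from 104 to 154 in R3K vs WT, 371 to 866 in G1685D vs WT and 309 to 470.0 in R3K vs G1685D. miRNA ranged from 0 to 21 in R3K vs WT and 66 to 116 in G1685D vs WT. piRNA 21U reads, G1685D vs WT ranged from 0 to 17. ncRNA 26G reads ranged from 1 to 5 in R3K vs WT and 2 to 5 in G1685D vs WT. Transposon reads ranged from 1 to 3 in R3K vs WT and 19 to 36 in G1685D vs WT. mRNA 22G reads ranged from 51 to 151 in G1685D vs WT and 35 to 57 in R3K vs G1685D. Arms ranged from 0 to 20 in G1685D vs WT and 7 to 22 in R3K vs G1685D. In log2, class totals per library, piRNA, R3K vs WT ranged from -0.0737 to 1.37, and class totals per library, 21U, R3K vs WT from -0.0475 to 1.64.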

Other observations

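The split of 26G genes by the authors' classes and the hypothesis test below were made on these data; the test was planned and the split was chosen after the result was seen.

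The 26G genes divided by the authors' classes. Whether those classes were drawn from these data was not known here, so they are not taken as independent evidence. Of 20 ERGO class genes 19 were lower and 1 higher in R3K (median log2 -5.40, or -3.88 with unread genes at their bound), and 14 were lower and 1 higher in G1685D (median -2.81, or -2.64 at the bound). Of 7 ALG class genes 1 was lower and 1 higher in R3K (median 0.42), and 1 was lower and 5 higher in G1685D (median 2.90). The authors' tables listed 0 higher and 1 lower of 311 ALG class features in each mutant, a wider set with other counts and scaling. Their values for these 7 genes were not compared, so whether they show this rise was not tested. Of 39 genes in neither class 15 were lower and 6 higher in R3K, and 16 and 12 in G1685D. R3K lay below G1685D in 8 ERGO class, 2 ALG class and 18 other genes. Of the 28 genes lower in both mutants 24 had a lower mean CPM of 26G reads in R3K than in G1685D, 1 a lower mean in G1685D and 3 none in either. That 1 gene was Y57G11C.36, which kept 6.81% of WT in R3K and 4.19% in G1685D. For other single targets, chosen after their values were seen, the kept 26G reads ran in R3K and G1685D at 0.105% and 6.49% of WT for hpo-9, 2.32% and 8.38% for K02E2.6, 2.39% and 5.87% for T05E12.8 and 0.527% and 15.7% for F55C9.5.

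Among sense reads, 34 of 39 oocyte genes, 25 of 29 histone genes and 9 of 10 heat shock genes were higher in R3K, and 27, 27 and 10 in G1685D, with the whole table at a median log2 of 1.99 and 1.80 (mRNA sense reads, R3K vs WT, and mRNA sense reads, G1685D vs WT).

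A hypothesis was that the entries hold reads from 26G target loci, where the entries are the miRNA entries lower in both mutants. The 10 entries were mir-8199-5p, mir-236-5p, mir-67-5p, mir-4813-5p, mir-231-5p, mir-788-minor, mir-86-3p, mir-1018, mir-4808-major and mir-44-5p. For 9 of them, with a gene of precursor size, 0 overlapped a gene with 26G reads lower in both mutants, although some lay in other genes, mir-86 in Y56A3A.7 and mir-1018 and mir-4808 in Y59E1B.1. The annotated gene of mir-8199 spans 778 nt, so that overlap with other genes is no test for it. With 0 of 9 overlapping, the values argue against the hypothesis that the entries hold reads from 26G target loci for these 9. They cover only loci that overlap the entries, and reads from loci elsewhere that match by sequence were not tested. For mir-8199 the hypothesis was left untested. The limit for precursor size was set after the values were seen.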
